A study of Saccharomyces cerevisiae with 19 samples.

How the data were processed

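Total RNA of budding yeast was measured on Affymetrix Yeast 2.0 arrays, with 1 array per strain and time point. The wild type had 10 arrays, taken every 12 h from 12 to 120 h of culture. The labelled sch9 mutant had 9 arrays, from 12 to 108 h; per the labels, the authors set aside its 120 h array after a quality check, and it was not used here. Cultures were started from saturated overnight cultures in SDC, a synthetic complete medium, and kept at 30 °C with shaking. RNA was isolated with acid phenol and labelled with biotin. Replicate cultures were not part of the design, so every p-value measures the spread of a difference or a trend over time points, not over independent cultures.

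The values deposited by the authors are probe set summaries on a log2 scale, between 5.76 and 15.02. The software, background correction and normalization behind them are not given in the sources used here. The medians of the deposited columns lay between 9.43 and 10.05, a range of 0.62. In the mutant columns at least 94.0% of the values ended in the same digits at the ninth decimal, against at most 0.0172% in any wild-type column, so the columns of the strains were not written in the same way. Raw intensities were not used here.

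Of the 5814 probe sets, 51 were controls and 265 named no gene. The other 5498 were matched to the annotation of the reference genome R64 by gene identifier, and 12 symbols were updated. For the 47 genes with several probe sets the one with the highest mean was kept, which gave 5449 genes. Among the probe sets kept for the 5449 genes 115 carry a suffix that marks sequence shared between genes, and genes read by these are called uncertain where they are named. Probe sets for fission yeast, which the array design also holds, were not used here.

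The written plan called for quantile normalization over the tested genes if the column medians differed by more than 0.1, which they did, so every value below is quantile-normalized unless it is called deposited. Differences are on the log2 scale, labelled mutant minus wild type. SCH9, the gene named as deleted, was compared at the 9 shared times with an exact permutation test of the signs of the time-matched differences, two-sided, whose smallest p is 0.00391. The same exact test was run on the mean of each gene list, with the Benjamini-Hochberg adjustment over the 37 lists. Genes were tested with limma 3.58.1 in R 4.3.3, as a strain term with the time points as blocks (8 residual degrees of freedom) and as a linear time trend in each strain and their difference, in log2 per day (15 residual degrees of freedom). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 5449 genes.

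Before the data were examined, 38 gene lists were fixed, among them markers of mating type, of the haploid state and of meiosis. The list of the mitochondrial genome had no measured member, and 37 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The genes to be named were set by a rule. SCH9 came first. For each limma result the rule took the 6 largest estimates in each direction among the genes past the threshold, for the strain difference only those with 1 sign at all 9 times. Of each list described it took up to 3 members with the smallest p, or 2 in each direction. All members of the marker gene list and of both mating lists could be named.

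The procedure was tested on simulated data with 5449 genes at the spread of the measured ones. Planted strain differences of 0.5 were found in 73% of cases and differences of 1 in 97%. Trends of 0.3 per day in the wild type were found in 79% of cases and trend differences of the same size in 52%. Outside the planted genes 11 passed for the strain difference, 7 for the wild-type trend and 9 for the trend difference. A planted shift of 0.5 in the iron regulon list was the only list called of 37. Genes and arrays were simulated as independent, while the estimated correlation within this list was 0.369 for the strain difference. The simulation therefore does not show how camera at the preset correlation behaves when members of a list move together.

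Alternatives set out in advance were the deposited values, median centring, cyclic loess, array weights, an intensity trend with a robust prior, each strain fitted alone, no time blocks, pairing with the wild type 12 h earlier or later, dim probe sets left out (a mean in the lower 25% of all genes, which left 4132 genes), an adjusted p under 0.01, a 2-fold minimum, every other time point, 36 h and later, log2 of hours, a spline with 3 degrees of freedom, and leaving out each time in turn. Alternatives chosen after the data were seen left out the times from 84 h on or added the 3' to 5' score of the control probe sets as a covariate; for the gene lists, median centring, cyclic loess, every other time point, 36 h and later, and KDX1 in place of MLP1 among the cell wall genes were also added then. Other orders or exchanges of the arrays were drawn 100 times. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.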

Results

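The series followed a wild-type yeast strain and a strain labelled as lacking SCH9, a protein kinase of nutrient signalling whose loss prolongs survival in stationary culture. Genome-wide RNA levels were read on 19 arrays, 10 of the wild type from 12 to 120 h and 9 of the labelled mutant from 12 to 108 h. The strains shared 9 time points. Each time point was a single array, and the number of arrays limits the precision of every value. The values of 5449 genes were tested.

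SCH9 itself (YHR205W) was lower in the labelled mutant at 8 of the 9 shared times, by a mean log2 difference of -0.52 ± 0.39 (SD, n = 9, exact permutation p = 0.00781). Its signal lay between 10.43 and 11.26 in the wild type and between 10.07 and 10.59 in the labelled mutant. At 12 h it was 0.16 higher in the labelled mutant, and at 36 h the difference was -1.19. The SCH9 signal never fell below percentile 57.8 of all genes in a labelled mutant array, so the probe set still gave signal there. In the deposited values the difference was -0.39 ± 0.63 (SD, n = 9, exact permutation p = 0.109). Where the probe set lies relative to the deleted part of the gene is not given in the sources used here, so its level does not check the strain label.

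URA3, a uracil biosynthesis gene widely used as a marker for gene deletions, separated the strains at every time. It was 1.78 ± 0.36 higher in the labelled mutant (SD, n = 9, higher at 9 of 9 times, exact permutation p = 0.00391), with signals of 9.41 to 10.19 there and 7.63 to 8.49 in the wild type. The list of auxotrophic and deletion marker genes had 3 of 7 measured members higher and 1 lower, and the same numbers adjusted over the list alone. ADE2 was higher by 0.77 and HIS3 by 0.58, and the difference of MET17 was -0.44. LEU2 (0.41), LYS2 (0.38) and CAN1 (0.01) did not pass. Without 12 h LEU2 passed at 0.72 (adjusted p = 0.00695) and LYS2 at 0.53 (adjusted p = 0.00293), and LYS2 also passed without 24 h, at 0.48 (adjusted p = 0.0254); with median centring LEU2 and CAN1 had the opposite sign, and CAN1 also with cyclic loess.

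**Figure D1:**
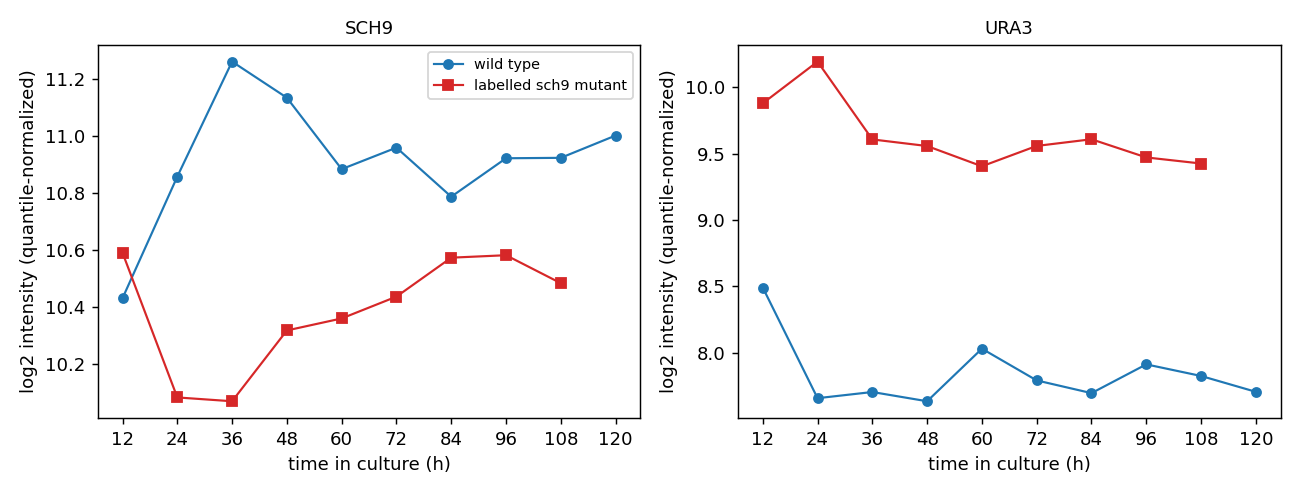
SCH9 (left) and URA3 (right) signal, as quantile-normalized log2 intensity, against time in culture in hours; each point is 1 array, blue circles the wild type and red squares the labelled sch9 mutant. SCH9 lay lower in the labelled mutant at 8 of 9 shared times, and the ranges of URA3 (7.63 to 8.49 and 9.41 to 10.19) did not overlap.

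The deposited signals of control probe sets differed between the strains over the course. In the wild type the deposited signal of the 3' probe set for 18S ribosomal RNA, which a poly(A)-primed labelling should hardly pick up, was 8.35 at 12 h, 8.62 at 48 h, 10.54 at 60 h, 13.77 at 84 h and 14.64 at 120 h. In the labelled mutant it stayed between 6.69 and 7.68. The paired difference was -3.72 ± 2.59 (SD, n = 9, lower at 9 of 9 times, exact permutation p = 0.00391). The probe set for the 5' end of 18S moved the same way over a smaller range: it was already at 12.22 at 12 h in the wild type and stood at 14.41 at 120 h, and its paired difference was -2.20 ± 0.92 (SD, n = 9, lower at 9 of 9 times, exact permutation p = 0.00391). That for 5.8S was 9.52 at 12 h and 13.43 at 120 h in the wild type, with a paired difference of -2.98 ± 1.40 (SD, n = 9, lower at 8 of 9 times, exact permutation p = 0.00781). Only that for the 3' end of 25S went otherwise: it was 11.51 at 12 h and 10.48 at 120 h in the wild type, and was 1.12 ± 0.97 higher in the labelled mutant (SD, n = 9, higher at 8 of 9 times, exact permutation p = 0.0195). The mean log2 difference between 3' and 5' probe sets of 10 control pairs, a score that grows as messages lose their 5' ends, went from 0.80 at 12 h to 1.44 at 120 h in the wild type. ACT1, SPT15 and SRB4 were each read by more of these pairs than the other genes, so they weigh more in the score. In the labelled mutant this score lay between 0.73 and 1.06, and the paired difference was -0.18 ± 0.20 (SD, n = 9, lower at 8 of 9 times, exact permutation p = 0.0352).

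**Figure D2:**
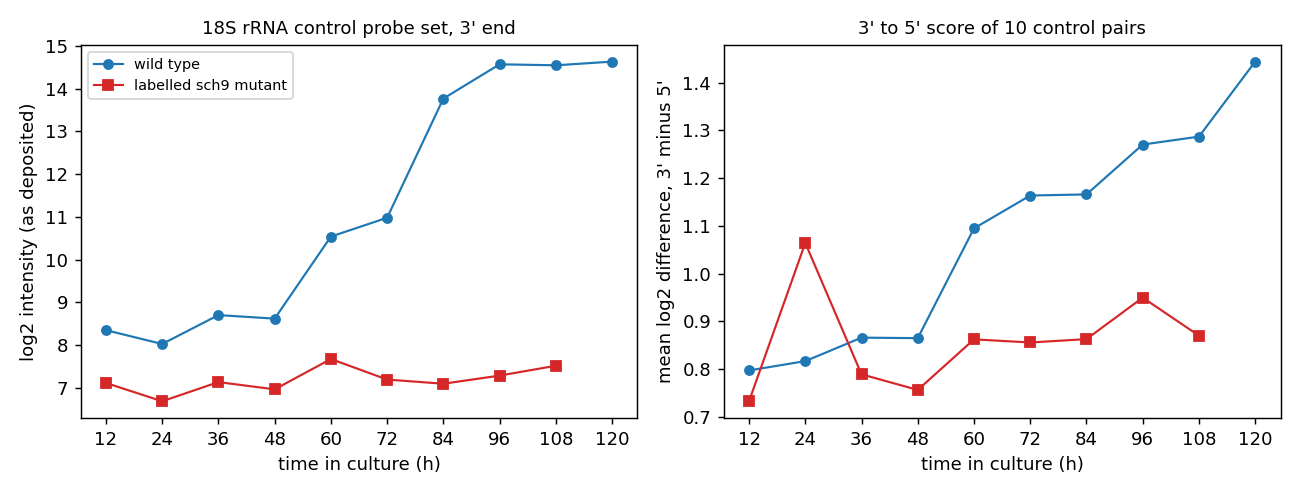
Deposited log2 signal of the 18S ribosomal RNA 3' probe set (left) and the mean log2 difference between 3' and 5' control probe sets (right) against time in culture in hours; each point is 1 array, blue circles the wild type and red squares the labelled sch9 mutant. The wild-type signal of the 18S 3' probe set stood at 8.62 at 48 h and 14.64 at 120 h, while that of the labelled mutant stayed at 6.69 to 7.68.

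The first comparison asked which genes differ between the strains at matched times. The uncharacterized gene YDL218W was higher in the labelled mutant by 4.16 (SE 0.44, adjusted p = 2.65e-05), and PMA2, a minor isoform of the plasma membrane proton pump, by 2.76 (SE 0.33, adjusted p = 5.56e-05). SIT1, a transporter of iron-siderophore complexes, was higher by 2.11 (SE 0.13), the iron permease gene FTR1 by 1.97 (SE 0.25) and its partner oxidase gene FET3 by 1.92 (SE 0.14). VBA3, an amino acid transporter gene, was higher by 2.30, read by a probe set shared with another sequence and so uncertain. Lower in the labelled mutant were the cell wall mannoprotein genes SRL1 at -3.27 (SE 0.35), CWP1 at -2.70 (SE 0.17) and TOS6 at -2.48 (SE 0.25). BTN2, a protein-sorting factor gene, differed by -2.61 (SE 0.19), YCL021W-A by -2.32 (SE 0.26) and ANB1, a hypoxic translation factor gene, by -2.25 (SE 0.29). Each of these 12 genes had 1 direction at all 9 times, which the naming rule required. Each call was kept when any single time was left out and under all 3 other scalings. The choice of large differences with 1 direction favours this, so it is no separate support.

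In all, 3225 of the 5449 genes (59.2%) passed, 1767 higher and 1458 lower in the labelled mutant. Most differences were small: the median size among these genes was 0.46, and 306 genes (97 higher, 209 lower) also differed at least 2-fold. All 9 shared times had the same sign for 1554 genes (28.5%), against 0.391% by chance if times were independent. They were not: the median correlation of successive differences was 0.22, where independent values gave -0.11 in simulation. The 0.391% is therefore no measure of chance here. Without the times from 84 h on, when the wild-type signal of the 18S 3' probe set was high, 2360 genes passed, and 2282 of these were among the 3225. The balance of the directions depended on the scaling: 66.3% of the genes past the threshold were higher in the deposited values and 38.8% after median centring. The median difference of all genes was 0.03 after quantile normalization, 0.17 in the deposited values and -0.09 after median centring.

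Genes for cytosolic ribosomal proteins, of the iron regulon and for histones were higher in the labelled mutant. Each of these 3 lists passed with camera at the preset correlation and had an adjusted p = 0.853 with an estimated correlation. Of 127 genes for cytosolic ribosomal proteins 107 were higher, 5 lower and 15 did not pass (107 higher and 6 lower adjusted over the list alone), with a mean difference of 0.53 that was positive at 9 of 9 times. RPL27B was higher by 1.42 and RPS11A by 1.32, while RPL9A (-0.45) and RPS27A (-0.47) were lower. Of 25 iron regulon genes 20 were higher, 1 lower and 4 did not pass (21 and 1 adjusted over the list alone). The mean of this list was 1.00, at 0.01 at 12 h and between 0.78 and 1.33 at the later times, and FRE3, a ferric reductase gene whose call was kept under 2 of the 3 other scalings, was the lower member at -0.39. Of 9 histone genes 6 were higher, none lower and 3 did not pass (6 higher and 1 lower adjusted over the list alone), HTB1 by 1.43, HHT1 by 0.82 and HHO1 by 0.61; their mean of 0.40 turned to -0.02 with median centring. The adjusted camera p was 8.85e-18 for the ribosomal proteins, 4.84e-05 for the iron regulon and 0.0471 for the histones. The histone call was lost without 12 h (adjusted p = 0.0714) or 24 h (adjusted p = 0.0583), in the deposited values (adjusted p = 0.593) and with median centring (adjusted p = 0.659). Other lists of protein synthesis did not pass: 17 of 50 translation factors and tRNA synthetases were higher and 9 lower (17 and 9 adjusted over the list alone; camera adjusted p = 0.859), 45 of 105 ribosome biogenesis genes were higher and 13 lower (44 and 12 adjusted over the list alone; camera adjusted p = 0.188), and 6 of 68 mitochondrial ribosomal proteins were higher and 19 lower (5 and 18 adjusted over the list alone; camera adjusted p = 0.0971). The mean of the last list was -0.12, but 0.10 in the deposited values. The 3' to 5' score was lower in the labelled mutant at 8 of the same 9 times.

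Lower lists were those of seripauperins, the cell wall, heat shock proteins and chaperones, trehalose and glycogen, the respiratory chain and amino acid biosynthesis. Each of these 6 lists passed with camera at the preset correlation and had an adjusted p = 0.853 with an estimated correlation. Of 13 seripauperin genes, a family of cell wall proteins with near-identical copies that share probe sets, 9 were lower, 1 higher and 3 did not pass (9 and 1 adjusted over the list alone); PAU4 stood at -1.45 and PAU18 at -1.18, and PAU7 at 0.50. Of 32 cell wall genes 14 were lower, 3 higher and 15 did not pass (13 and 3 adjusted over the list alone), among them SCW10 at -1.22, with EXG1 (0.64) higher. The list also holds MLP1 (0.56), which is now the symbol of a nuclear pore gene and was once also used for the cell wall pathway gene KDX1. With KDX1 (0.03, adjusted p = 0.864) in its place, an alternative chosen after the data were seen, 14 were lower, 2 higher and 16 did not pass (12 and 2 adjusted over the list alone), with a mean of -0.44 and an adjusted camera p = 0.0136 (0.853 with an estimated correlation). Of 31 heat shock proteins and chaperones 17 were lower, 3 higher and 11 did not pass (18 and 3 adjusted over the list alone); HSP31 differed by -1.30 and SSC1 by -0.51, against 1.41 for SSA3 and 0.57 for SSB2. Of 22 trehalose and glycogen genes 13 were lower, 2 higher and 7 did not pass (13 and 2 adjusted over the list alone), with the glycogen synthase genes GSY1 at -1.88 and GSY2 at -0.99. Of 37 genes of the respiratory chain and ATP synthase 19 were lower, 3 higher and 15 did not pass (19 and 4 adjusted over the list alone), with QCR9 at -0.86 and CYT1 at -0.66, and ATP14 higher at 0.73. Of 57 amino acid biosynthesis genes 21 were lower, 5 higher and 31 did not pass (21 and 5 adjusted over the list alone), with GLT1 at -1.18, LYS1 at -1.12 and ILV5 higher at 0.96. The calls of EXG1, SSB2 and ATP14 were kept under 2 of the 3 other scalings. Other lists of stress genes did not pass: 10 of 43 stress-induced genes of the general stress regulators Msn2, Msn4 and Gis1 were higher and 18 lower (10 and 18 adjusted over the list alone; camera adjusted p = 0.166), and 8 of 31 antioxidant genes were higher and 7 lower (8 and 7 adjusted over the list alone; camera adjusted p = 0.577).

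The mean differences of these lower lists were -0.63 for seripauperins, -0.42 for the cell wall, -0.32 for heat shock proteins, -0.41 for trehalose and glycogen, -0.25 for the respiratory chain and -0.21 for amino acid biosynthesis. Their adjusted camera p-values ran from 0.00168 for seripauperins to 0.0196 for amino acid biosynthesis. The call was lost without 12 h for the cell wall (adjusted p = 0.0714) and for trehalose and glycogen (adjusted p = 0.0597), and without 24 h for amino acid biosynthesis, whose mean was then -0.13 (adjusted p = 0.214). With cyclic loess the calls of the respiratory chain (adjusted p = 0.0923), of amino acid biosynthesis (adjusted p = 0.0570) and of the cell wall (adjusted p = 0.0518) were lost. With median centring the mean of the ribosomal proteins was 0.11, that of the heat shock proteins -0.82, of the respiratory chain -0.77, of the cell wall -0.78, of trehalose and glycogen -0.70 and of amino acid biosynthesis -0.51. With the 3' to 5' score as a covariate the calls of the heat shock proteins (adjusted p = 0.062), of trehalose and glycogen (adjusted p = 0.128) and of the histones (adjusted p = 0.062) were lost; their means were then -0.16, -0.15 and 0.36. The exact permutation test of each list mean over the 9 times, which compares a list with 0 and not with other genes, passed for 21 of the 37 lists, these 9 included.

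**Figure D3:**
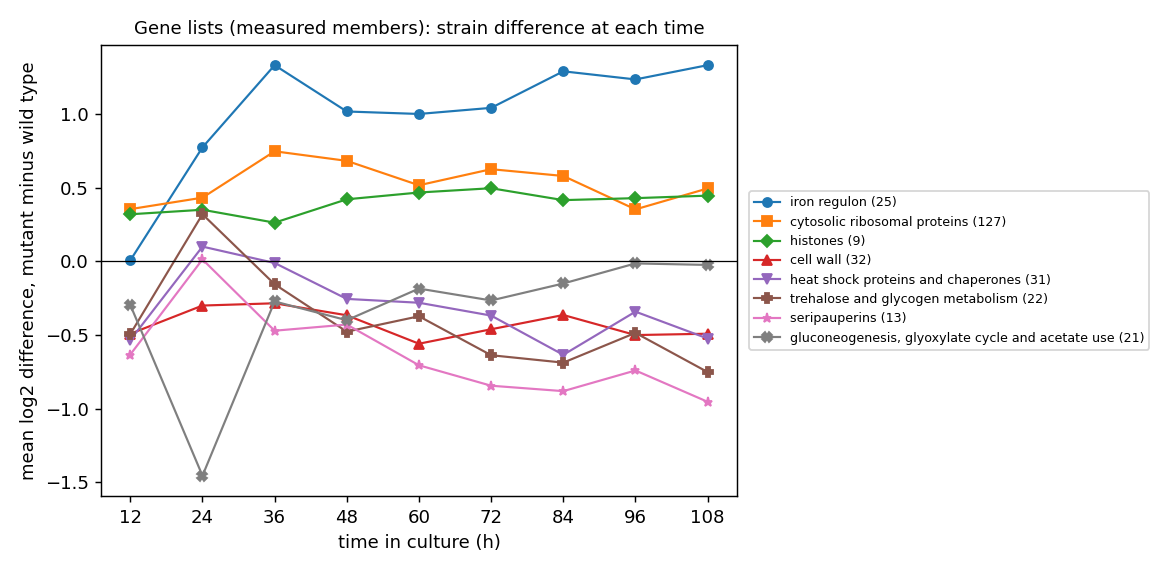
Mean log2 difference, labelled mutant minus wild type, of 8 gene lists (number of measured members in brackets) against time in culture in hours; each point is the mean over the list in 1 pair of arrays. The iron regulon stood at 0.01 at 12 h and at 0.78 to 1.33 later, the cell wall and gluconeogenesis lists were below 0 at all 9 times, and the histone mean of 0.40 turned to -0.02 with median centring.

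Genes that mark cell type also differed. The alpha-factor genes MF(ALPHA)2 (-1.91) and MF(ALPHA)1 (-1.32) and the alpha-agglutinin gene SAG1 (-1.36) were lower in the labelled mutant. BAR1 was 0.43 higher, although it stood at -0.06 with median centring, AGA2 was 0.39 higher (kept under 2 of the 3 other scalings), and ASG7 was 0.18 higher but -0.15 in the deposited values and -0.40 with median centring. STE2 (0.17), STE3 (-0.06), STE6 (-0.14), MFA1 (-0.22) and MFA2 (-0.14) did not pass, although MFA1 did without 24 h (-0.32, adjusted p = 0.00772); STE3 and STE6 had the opposite sign in the deposited values. The list of genes specific to mating type a or alpha had 3 of 11 members higher and 3 lower, and the same numbers adjusted over the list alone. Of 12 genes of the haploid mating pathway, which diploid cells turn off, 3 were higher and 4 lower (3 and 4 adjusted over the list alone), among them STE18 at -0.56 (kept under 2 of the 3 other scalings) and HO at -0.54. Of 29 meiosis and sporulation genes 7 were higher and 12 lower (8 and 13 adjusted over the list alone), with SPS100 at 2.52, ZIP1 at 0.71, IME2 at -1.16 and SPS22 at -0.62. None of these 3 lists passed with camera, and the haploid list mean of -0.11 turned to 0.11 in the deposited values.

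The second comparison asked which genes changed steadily with time in the wild type. The largest rises per day were those of the uncharacterized genes YOR032W-A (0.69, SE 0.13) and YLR012C (0.60, SE 0.17), of ROG3, an arrestin-related gene (0.63, SE 0.16), and of NCA3 (0.54), FAT3 (0.51) and RRT8 (0.51). The largest falls were those of RMT2 (-0.35, SE 0.09), the mitochondrial ribosomal protein genes MRPL17 (-0.34) and MRPS28 (-0.31), the ribosome biogenesis gene MRD1 (-0.34), the phosphate regulator gene PHO4 (-0.33) and the kinetochore gene NNF1 (-0.31). In all 614 genes passed, 262 rising and 352 falling. Single times and the scaling decided some of these calls. With single times left out the slopes ran from 0.44 to 0.79 for YOR032W-A, 0.34 to 0.75 for ROG3 and 0.35 to 0.85 for YLR012C. The slope of RRT8 ran from 0.30 to 0.60 and that of MRD1 from -0.40 to -0.20. Under the 3 other scalings RMT2 and MRD1 lost the call each time, YLR012C kept it in 1 and PHO4 in 2. ROG3 did not pass without 24 h (adjusted p = 0.0628), MRD1 without 24, 96 or 108 h (0.0528 to 0.0696), PHO4 without 24, 72, 84, 96 or 108 h (0.0517 to 0.108) and YLR012C without 12, 24, 36, 84, 96 or 108 h (0.0535 to 0.117); with array weights YLR012C had a slope of -0.09.

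Among the lists, RNA levels of the mitochondrial ribosomal protein and proteasome genes passed downward over time in the wild type, and those of the seripauperin genes upward. With an estimated correlation the first had an adjusted p = 0.959 and the other 2 lists an adjusted p = 0.436. Of 68 mitochondrial ribosomal protein genes 18 fell, none rose and 50 did not pass (36 fell and none rose adjusted over the list alone), with a mean slope of -0.13 and MRPL40 at -0.22 per day. Of 33 proteasome genes 19 fell, none rose and 14 did not pass (24 fell and none rose adjusted over the list alone), with a mean of -0.13, PRE9 at -0.21, RPN1 at -0.17 (kept under 2 of the 3 other scalings) and PRE1 at -0.15. Of 13 seripauperin genes 4 rose, 1 fell and 8 did not pass (10 and 1 adjusted over the list alone), with PAU9 at 0.22 and a mean of 0.15. The adjusted camera p was 2.62e-13, 1.21e-13 and 0.000194. Another 9 of the 12 lists that passed did not keep the call without 12 h, with an adjusted p = 0.959 with an estimated correlation for each, and gluconeogenesis, at 0.26 per day, then passed in the other direction (-0.11, adjusted p = 0.0383). The 3' to 5' score and the signal of the 18S 3' probe set climbed over the same hours as these lists moved. With that score as a covariate the proteasome call was kept and the calls of the mitochondrial ribosomal proteins and of the seripauperins were not (adjusted p = 0.840 for each). Because the score climbed with time, the lost calls cannot tell a trend from an effect of RNA quality.

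The number of wild-type trends depended on single times. Without 12 h 2262 genes passed, and without 24, 72, 84, 96 or 108 h 319, 400, 363, 306 and 325 passed. Without 120 h it was 506, and without 36, 48 or 60 h it lay between 478 and 548. Without the times from 84 h on 48 genes passed, and with the 3' to 5' score as a covariate 0 passed with limma, where 574 had an unadjusted p under 0.05. In the wild type that score climbed with the hours, from 0.80 at 12 h to 1.44 at 120 h. A fit with both can hardly separate a trend from the score, so this loss does not show that RNA quality was the source. With every other time point 0 passed with limma, where 611 had an unadjusted p under 0.05. The directions also moved with the scaling, at 80 rising and 428 falling in the deposited values and 401 rising and 189 falling with median centring.

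The third comparison asked the same of the labelled mutant. Among the largest rises were those of STL1, a glycerol importer gene, by 1.12 per day (SE 0.27), the sulphate permease gene SUL1 by 0.94 (SE 0.11), the phosphate transporter gene PHO84 by 0.87 (SE 0.13) and the ammonium permease gene MEP1 by 0.84 (SE 0.09). DAK2, a dihydroxyacetone kinase gene, rose by 0.91 and TIS11, which acts on messages of iron-using proteins, by 0.79. With single times left out the TIS11 slope ran from 0.33 to 0.95. The largest falls were those of MF(ALPHA)1 (-1.06, SE 0.07), SRL1 (-0.80, SE 0.16), INO1, for inositol synthesis (-0.76, SE 0.12), SAG1 (-0.66), YIL082W-A, a transposon sequence with a shared probe set and so uncertain (-0.65), and ANB1 (-0.63). With single times left out the slopes ran from -0.95 to -0.41 for SRL1, -0.76 to -0.38 for SAG1 and -0.73 to -0.30 for ANB1. Those of MF(ALPHA)1 (-1.15 to -1.01) and INO1 (-0.89 to -0.63) moved less. In all 546 genes passed, 293 rising and 253 falling. STL1 did not pass without 24 h (adjusted p = 0.0566).

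Among the lists, RNA levels of the iron regulon genes passed upward over time in the labelled mutant and those of the proteasome genes downward, with an adjusted p = 0.344 and an adjusted p = 0.527 under an estimated correlation. Of 25 iron regulon genes 15 rose, none fell and 10 did not pass (22 rose and none fell adjusted over the list alone), with a mean of 0.35 per day, FRE6 at 0.38, FRE5 at 0.35 and FRE4 at 0.25. Of 33 proteasome genes 11 fell, none rose and 22 did not pass (16 fell and none rose adjusted over the list alone), with PRE9 at -0.29, PRE5 at -0.16 and RPN9 at -0.19, the last 2 kept under 2 of the 3 other scalings. Of 19 genes of the tricarboxylic acid cycle 4 rose and none fell (8 rose and 1 fell adjusted over the list alone), with FUM1 at 0.29 and IDH2 at 0.21, and an adjusted p = 0.594 with an estimated correlation. FUM1 and IDH2 each kept the call under only 1 of the 3 other scalings, and the list call was lost in the deposited values (adjusted p = 0.0665) and with median centring (adjusted p = 0.0511). Of 21 genes of gluconeogenesis and acetate use 2 rose and none fell (8 rose and none fell adjusted over the list alone), with CIT2 at 0.50 and ADH2 at 0.63 and an adjusted p = 0.650 with an estimated correlation. CIT2 passed under 2 of the 3 other scalings and did not pass without 24 or 84 h (adjusted p 0.0527 and 0.0581), and ADH2 not without 12, 24, 84 or 96 h (0.0556 to 0.0703). With single times left out the slopes ran from 0.21 to 0.61 for CIT2 and from 0.34 to 0.76 for ADH2. Of 12 haploid mating pathway genes 3 fell and none rose (5 fell and 1 rose adjusted over the list alone), with NEJ1 at -0.23 and STE4 at -0.37, and an adjusted p = 0.594 with an estimated correlation.

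These 5 lists kept their calls whichever single time was left out, and the other 13 of the 18 lists that passed did not. From 36 h on, however, the slope of gluconeogenesis turned to -0.016 (adjusted p = 0.893) and the haploid mating pathway, at -0.090, lost its call (adjusted p = 0.0672). Of 32 genes of nitrogen catabolite repression 5 rose and none fell (6 rose and none fell adjusted over the list alone), with CAR1 at 0.45, and an adjusted p = 0.344 with an estimated correlation; the call was lost without 12 h (adjusted p = 0.120). Of 17 phosphate regulon genes 2 rose and 1 fell (6 and 2 adjusted over the list alone), with PHO89 at 0.72, and an adjusted p = 0.344 with an estimated correlation; the call was lost without 12 h (adjusted p = 0.120), 24 h (0.0510) or 96 h (0.0599). Of 43 stress-induced genes of Msn2, Msn4 and Gis1 none rose and 1 fell (none adjusted over the list alone). Their mean slope of 0.15 passed with camera, had an adjusted p = 0.872 with an estimated correlation, and turned to -0.19 without 12 h (adjusted p = 3.68e-09). The number of genes with a trend was 1564 without 12 h and 342, 282 and 314 without 72, 84 and 96 h. Without the times from 84 h on it was 31, and with every other time point 20.

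The fourth comparison asked which trends differed between the strains, by the difference in slope, labelled mutant minus wild type. The largest upward differences were those of PHO84 by 1.05 per day (SE 0.18, adjusted p = 0.00284), SUL1 by 0.85 (SE 0.14, adjusted p = 0.0026), PHO89 by 0.71 and MEP1 by 0.61 (SE 0.11, adjusted p = 0.00714). HBN1 diverged by 0.58 and GDH1, the glutamate dehydrogenase gene of ammonium assimilation, by 0.57. MF(ALPHA)1 (-0.86, SE 0.10) and INO1 (-0.78, SE 0.15) diverged downward. So did the transposon-related or repeated sequences YER138W-A (-0.82), YDR261C-D (-0.81), YLR154C-H (-0.77) and YGR109W-B (-0.76), of which the first 3 have shared probe sets and are uncertain; YLR154C-H lies in the ribosomal DNA, and the signal of the 18S 3' probe set climbed in the wild type over the same hours. In all 156 genes passed, 61 upward and 95 downward. PHO89 did not pass without 96, 108 or 120 h (adjusted p 0.0507 to 0.0841), and GDH1 not without 24, 84 or 108 h (0.0568 to 0.0684).

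Among the lists, the iron regulon diverged upward, with 3 of 25 members past the test upward and none downward (6 and none adjusted over the list alone), FTH1 at 0.38, FRE5 at 0.35 and FET5 at 0.25, and an adjusted p = 0.803 with an estimated correlation. Under the 3 other scalings FET5 lost its call each time, FTH1 kept it in 1 and FRE5 in 2. The list call was kept whichever time was left out, but each member lost its call without some times, FTH1 without 24, 84, 96, 108 or 120 h (adjusted p 0.0507 to 0.0954). FRE5 lost it without 24, 72, 84, 96 or 120 h (0.0545 to 0.117), and FET5 without 24 h or any of the times from 48 h on (0.0592 to 0.151). Both mating lists diverged downward, those specific to mating type a or alpha with 2 of 11 members past the test downward (2 adjusted over the list alone; adjusted p = 0.620 with an estimated correlation; call lost with cyclic loess, adjusted p = 0.0831) and the haploid pathway with 1 of 12 (1 adjusted over the list alone; adjusted p = 0.803 with an estimated correlation). SAG1 (-0.70) passed in the full set and did not pass without any of the times from 24 h on (adjusted p 0.0612 to 0.139). The trehalose and glycogen list diverged downward with 2 of 22 members (2 adjusted over the list alone), GPH1 at -0.63 and UGP1 at -0.44. It had an adjusted p = 0.839 with an estimated correlation, and its call was lost without 24 h (adjusted p = 0.105) or 108 h (adjusted p = 0.0844). With the 3' to 5' score as a covariate its difference turned to 0.068 (adjusted p = 0.678). The mitochondrial ribosomal proteins had a mean difference of 0.12 with 0 of 68 members past the test in limma (0 adjusted over the list alone), where 917 of all genes had an unadjusted p under 0.05. This list had an adjusted p = 5.42e-08 with camera and an adjusted p = 0.803 with an estimated correlation, and its call was lost with the 3' to 5' score as a covariate (adjusted p = 0.977).

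The count of 156 rested on single times as well. It was 1732 without 12 h, and 74, 70, 58, 63, 58 and 100 without 24, 72, 84, 96, 108 and 120 h. Without the times from 84 h on 9 genes passed. With every other time point, or with the 3' to 5' score as a covariate, 0 passed with limma, where 232 and 435 genes had an unadjusted p under 0.05. The score climbed with time in the wild type, so a fit with it can hardly separate a trend from the score. The same limit holds for the list results with this covariate. The direction was 68 upward and 43 downward in the deposited values, and 36 upward and 96 downward with median centring.

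**Figure D4:**
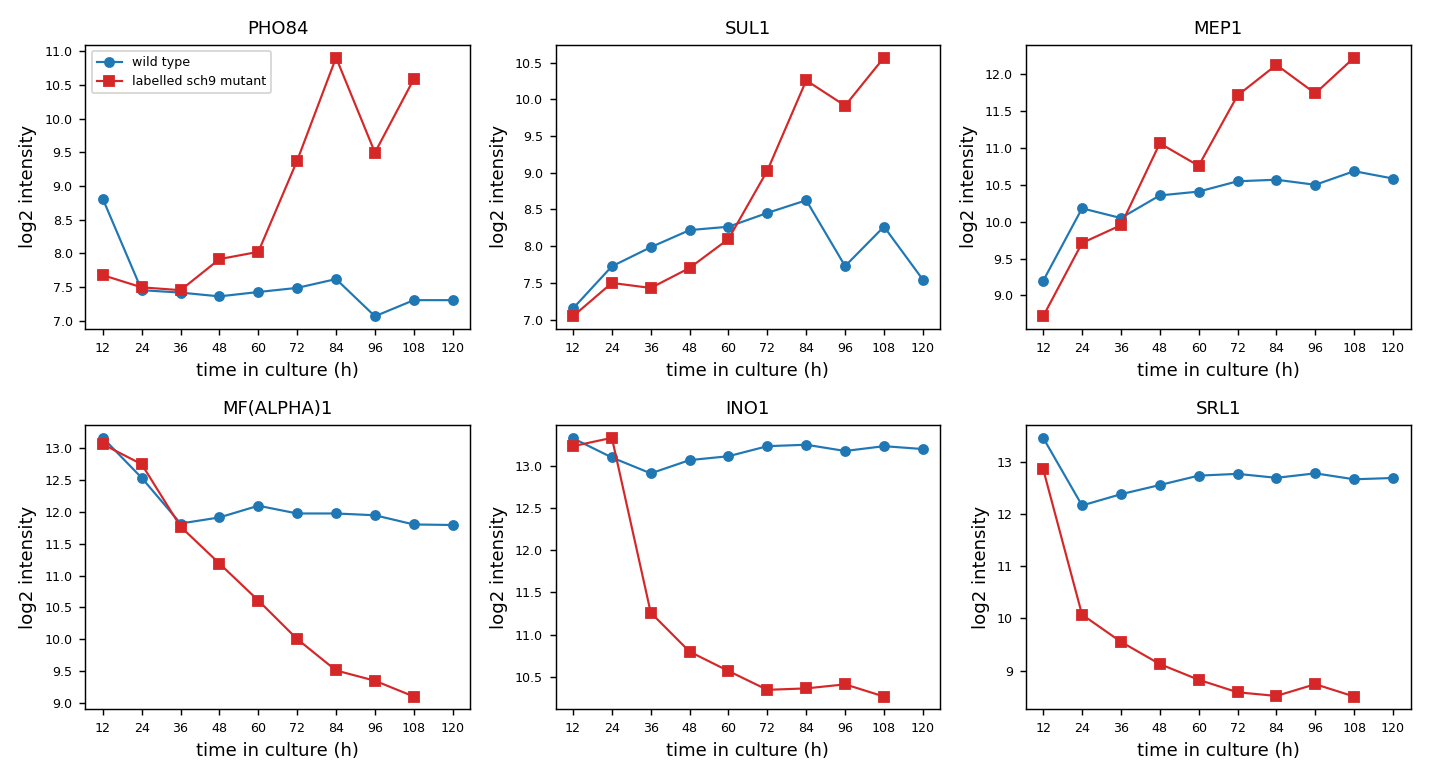
Quantile-normalized log2 intensity of PHO84, SUL1, MEP1, MF(ALPHA)1, INO1 and SRL1 against time in culture in hours; each point is 1 array, blue circles the wild type and red squares the labelled sch9 mutant. PHO84, SUL1 and MEP1 rose in the labelled mutant, by 0.87, 0.94 and 0.84 per day, and MF(ALPHA)1, INO1 and SRL1 fell there.

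Trends were partly shared by the strains. In both strains 54 genes rose (14.1 if calls were independent) and 44 fell (16.3), and 11 went in opposite directions (31.1). Both slopes of a gene share a single estimate of its spread, so calls need not be independent even without a shared trend. A shared spread would raise calls in the same and in opposite directions alike, and opposite calls lay below the number for independence. NNF1 (-0.31 per day in the wild type and -0.21 in the labelled mutant) and PRE9 (-0.21 and -0.29) fell in both. Slopes of the strains correlated across genes (Pearson r 0.48, Spearman rho 0.45), and genes are not independent replicates.

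Both strains changed most between 12 and 24 h, when 1265 genes changed at least 2-fold in the wild type and 1598 in the labelled mutant. At later steps 0 to 54 genes did so in the wild type and 10 to 169 in the labelled mutant. The profile of the labelled mutant at 12 h was closest to the wild type at 12 h (correlation across centred genes 0.86). The closest array was that of the same hour for 2 of the 9 mutant arrays. Genes were centred over the arrays of both strains, which sets the later arrays of the strains apart, so no lag is read from this number.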

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

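The tests of mislabelled single arrays and of a probe set outside the deleted part, and the exchange of the 12 h pair alone, were chosen after the result was seen.

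The first pattern is that 3225 of 5449 genes differed between the strains. Exchanging the arrays within pairs gave as many genes in 1 of 100 splits, the real one included. Replicate cultures were not part of the design, so this exchange cannot exclude a chance difference between the cultures. The differences at successive times were also not independent (median correlation 0.22, where independent values gave -0.11 in simulation). The highest other count was 2894, from exchanging every pair except that of 12 h, which is the same as exchanging the 12 h pair alone. A difference in RNA quality that goes with the 3' to 5' score alone does not account for the differences at 36 and 48 h. Gene differences at these times, when the scores were nearly alike, followed those at 84 to 108 h with a slope of 0.813. The ratio of the score differences was 0.267. The scores were also alike at 12 h (difference -0.065), when the profiles of the strains were close (correlation across centred genes 0.86). At 24 h the score was 0.25 higher in the labelled mutant. Neither 12 h nor 24 h was part of the test. The deposited signals of ribosomal RNA control probe sets were not alike at 36 and 48 h. Their differences, labelled mutant minus wild type, ran from -3.19 to 1.84 at 36 h and from -3.51 to 1.78 at 48 h. The test therefore cannot exclude an RNA quality difference that the score does not read. Strain differences correlated across 47 genes between 2 probe sets of the same gene (r 0.674, rho 0.759), although genes are not independent replicates. This argues against independent offsets of single probe sets as the only source, but does not exclude separate processing of the strains. The 1st percentile of the deposited values lay between 6.72 and 6.79 in the wild-type arrays and between 6.40 and 6.44 in the labelled mutant arrays. What stays open is the strain itself, which may be the source but is untested. Also open are a chance difference between cultures, a lag of 12 h and an RNA quality difference that the score does not read. An RNA quality difference that goes with the score at times other than 36 and 48 h is open too. The same holds for any difference in how the columns of the strains were made. The design does not separate these from the strain.

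The second pattern is the signal of the 18S 3' probe set in the late wild-type arrays, outside the main measurement: it lay 5.96 higher at 84 to 120 h than at 12 to 48 h, against 2.31 for the 5.8S, 1.26 for the 18S 5' and 0.12 for the 25S 3' probe set. The 18S 5' probe set already averaged 13.00 at 12 to 48 h, and the highest of all deposited values was 15.02, so it had little room to climb. A new labelling or array batch from 84 h is argued against by the genes that changed at least 1.5-fold between 72 and 84 h, which were 9, below all other steps from 60 h on (40 to 148). A batch change between 48 and 60 h was not tested. At that step 251 genes changed at least 1.5-fold in the wild type, and the signal of the 18S 3' probe set went from 8.62 to 10.54. RNA degradation may contribute and cannot be told apart from other sources, because over the 9 steps the changes in this signal and in the 3' to 5' score had r 0.232 (exact permutation p = 0.562) and rho 0.35 (exact permutation p = 0.359). Without the 2 steps farthest from the median r was 0.432. No biological explanation was tested.

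The third pattern is the SCH9 signal that remained in the labelled mutant arrays. Mislabelled single arrays are argued against by URA3, whose lowest signal in the labelled mutant lay 0.915 above its highest in the wild type, where the SD within a strain was at most 0.259; a swap of the 2 whole series would not be seen this way. That the probe set reads sequence outside the deleted part may explain it and cannot be told apart from transcript of an intact gene, because the lowest percentile of SCH9 in these arrays was 57.8 and the position of the probes is not given in the sources used here.

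Other values stood apart from the rest of their group. Single values far from the others, by Dixon's test, were found in 12 of 47 groups, where 2.35 would be reached by chance if groups and times were independent. Most groups were list means over the same pairs of arrays, so 1 unusual pair can flag several lists. The 12 groups are therefore no measured excess over chance. URA3 in the wild type was 8.49 at 12 h. Between 12 and 24 h 1265 genes changed at least 2-fold in the wild type, and 1598 in the labelled mutant. At 12 h the list differences between the strains stood apart for glycolysis and fermentation (-0.39), glycerol metabolism (-0.35), autophagy (-0.24), the iron regulon (0.0077), the unfolded protein response (-0.77) and nutrient signalling (-0.035). At 24 h they stood apart for gluconeogenesis (-1.45), amino acid biosynthesis (-0.83) and meiosis and sporulation (0.43).

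Trends that differed between the strains, by the test of the difference in slope, were those of 156 genes and 11 lists. Upward differences per day were those of mitochondrial ribosomal proteins (0.12), gluconeogenesis (0.27), amino acid biosynthesis (0.070, but -0.011 with median centring), sulphur amino acid metabolism (0.16) and the iron regulon (0.24). Downward differences were those of trehalose and glycogen (-0.13), ergosterol biosynthesis (-0.092), mitosis and cytokinesis (-0.14), seripauperins (-0.15), mating type (-0.25) and the haploid mating pathway (-0.20). No list kept its call with an estimated correlation. With the 3' to 5' score as a covariate amino acid biosynthesis (-0.11), sulphur amino acid metabolism (-0.0047), trehalose and glycogen (0.068) and seripauperins (0.029) had the opposite direction. As the score climbed with time in the wild type, that fit can hardly separate a trend from the score. Without 24 h the calls of gluconeogenesis (adjusted p = 0.0890), amino acid biosynthesis (0.713), sulphur amino acid metabolism (0.105), trehalose and glycogen (0.105) and seripauperins (0.0681) were lost. The calls of gluconeogenesis (0.228) and ergosterol biosynthesis (0.0881) were lost without 120 h. Without 108 h those of ergosterol biosynthesis (0.0549), seripauperins (0.0556) and trehalose and glycogen (0.0844) were lost, and ergosterol biosynthesis also lost its call without 36 h (0.0851) or 48 h (0.0675).

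Among probe sets outside the tested genes, the control probe sets for URA3 were 1.98 higher in the labelled mutant. Of 265 probe sets without a gene name 142 differed between the strains, 67 higher and 75 lower.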

How the results depend on the processing

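Leaving out the times from 84 h on and adding the 3' to 5' score as a covariate were chosen after the data were seen, as were, for the lists, median centring, cyclic loess, every other time point, 36 h and later, and KDX1 in place of MLP1 in the cell wall list. The cause was not tested for any value below except where fewer genes or times were used by construction. Of the named genes, 4492 values kept their side of the threshold, 44 of these with the opposite sign and no call on either side; 879 lost the call, 147 gained one and 14 reversed with a call on at least 1 side. For the lists that passed 729 kept, 180 lost and 33 reversed.

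For the strain difference, 1989 genes passed with every other time point and 306 at a 2-fold minimum, which use fewer times or a stricter limit. SCH9 stood at -0.39 in the deposited values (exact permutation p = 0.109) and at -0.64 with median centring. The lists that passed were 18 in the deposited values, 17 with median centring, 16 without the times from 84 h on and 0 of 37 with camera and an estimated correlation, against 9. The exact list test passed for 13 lists against the wild type 12 h earlier, against 21. Genes reversed with a call on at least 1 side were ASG7 (-0.15 deposited, -0.40 median-centred), BAR1 (-0.059) and CYS4 (-0.12) with median centring, FAR1 with array weights (-0.27), and with the score as a covariate CAN1 (-0.24) and STE4 (0.018).

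For the wild-type trend the count of 614 became 392 with dim probe sets left out, 158 at adjusted p under 0.01, 1603 with array weights, 2430 from 36 h on, 1285 on log2 of hours, 2254 with a spline, 48 without the times from 84 h on, 0 with every other time point (limma, 611 at unadjusted p under 0.05), 0 with the score as a covariate (574), and 306 to 2262 with single times left out. The lists were 21 deposited, 20 with every other time point, 22 without the times from 84 h on and 0 with an estimated correlation, against 12. From 36 h on camera, which reads a list against the other genes, reversed ribosome biogenesis (0.014), translation factors (0.059), gluconeogenesis (-0.12), heat shock proteins (0.00084) and the stress-induced genes (0.0041). With the score as a covariate it reversed mitochondrial ribosomal proteins (-0.0034), ribosome biogenesis (0.055), RNA polymerases I and III (0.025), translation factors (0.045), stress-induced genes (-0.19), trehalose and glycogen (-0.077) and seripauperins (-0.045). With single times left out the slopes ran from -0.11 to 0.36 for gluconeogenesis, -0.0089 to 0.12 for the tricarboxylic acid cycle and -0.12 to 0.029 for translation factors. YLR012C reversed with array weights (-0.086), and with the covariate RPC37 (0.060), PIG1 (-0.052) and PAU9 (-0.029) did.

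For the trend in the labelled mutant the count of 546 became 210 at adjusted p under 0.01, 1657 with array weights, 1228 from 36 h on, 1440 on log2 of hours, 1766 with a spline, 20 with every other time point, 31 without the times from 84 h on, and 282 to 1564 with single times left out. With an estimated correlation 0 of the 18 lists passed. From 36 h on camera reversed ribosome biogenesis (0.053), RNA polymerases I and III (0.0099), translation factors (0.0098), gluconeogenesis (-0.016), stress-induced genes (-0.14), autophagy (-0.071) and mitosis (0.0094). With single times left out the slopes ran from -0.25 to 0.047 for ribosome biogenesis, -0.15 to 0.013 for RNA polymerases I and III, -0.20 to 0.034 for translation factors, -0.19 to 0.28 for stress-induced genes, -0.067 to 0.16 for autophagy and -0.13 to 0.0080 for DNA replication. SAM2 reversed from 36 h on (0.10) and with array weights (0.050), and CIT2 from 36 h on (-0.0015).

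For the difference in trend the count of 156 became 37 at adjusted p under 0.01, 1533 with array weights, 1617 from 36 h on, 280 on log2 of hours, 390 with a spline, 9 without the times from 84 h on, 0 with every other time point (limma, 232 at unadjusted p under 0.05), 0 with the score as a covariate (435), and 58 to 1732 with single times left out. The lists were 17 deposited, 18 with median centring, 7 with dim probe sets left out, 4 with every other time point, 17 from 36 h on, 3 without the times from 84 h on, 17 with the covariate, 0 with an estimated correlation and 8 to 20 with single times left out, against 11. Amino acid biosynthesis reversed from 36 h on (-0.013) and with the covariate (-0.11), as did sulphur amino acid metabolism (-0.0047), trehalose and glycogen (0.068) and seripauperins (0.029) with the covariate. The wild-type change from 12 to 24 h covered 2542 genes at a 1.5-fold minimum, against 1265. Dim signals limit what can be seen: 4132 of the 5449 genes lay above the lower 25% taken as dim.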

Other observations

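The correlation of successive times and the ratio over the same 8 arrays were computed after the data were seen, and the lists described here were chosen from those that passed the exact test and were not yet described.

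Several gene groups not described above differed between the strains over the 9 shared times by the exact permutation test of the list mean. Glycerol metabolism was higher in the labelled mutant by 0.42 ± 0.30 (SD, n = 9, 8 of 9 times, adjusted exact p = 0.0193), with 7 of 12 members higher and 1 lower (7 and 1 adjusted over the list alone). GPP1 and GPP2, the glycerol phosphatase genes, were higher by 1.56 and 1.08, and GPD2, a glycerol phosphate dehydrogenase gene, stood at -0.67. Genes of nutrient signalling around SCH9 were higher by 0.17 ± 0.09 (SD, n = 9, 8 of 9 times, adjusted exact p = 0.0193), with 18 of 40 members higher and 10 lower (19 and 11 adjusted over the list alone). The kinase genes RIM15 and TOR1 were higher by 1.27 and 0.92, and DOT6 (-0.81) and RAS2 (-0.53) were lower. Sulphur amino acid metabolism was lower by a mean of -0.40 ± 0.33 (SD, n = 9, 9 of 9 times, adjusted exact p = 0.0145), with 10 of 27 members lower and 3 higher (10 and 3 adjusted over the list alone); CYS3 stood at -1.72, MUP3 at -1.54 and STR2 at 0.31. With median centring the means of glycerol metabolism and nutrient signalling were 0.11 and 0.038. None of these 3 lists passed with camera, which compares a list with the other genes (adjusted p = 0.251, 0.258 and 0.0657).

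A lag or lead of the labelled mutant by 12 h was tested as a hypothesis. Set against the wild type 12 h earlier, 2476 genes passed, and 12 h later 2818 did, which are 0.768 and 0.874 times the count at matched times. The earlier pairing has 8 pairs, without the mutant array of 12 h, and against the same 8 arrays at matched times (3478 genes) its ratio was 0.712. By either count the lower ratio lay between the bounds fixed for and against a lag, so a lag that may account for part of the difference cannot be told apart from a strain difference.

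An extra copy of a whole chromosome in either strain was tested as well. The chromosome median farthest from 0 was 0.0882, and none of the chromosome medians came near the 1.5-fold change that 1 extra copy would give at the least.

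The counts of trends were set against other orders or exchanges of the arrays. For the wild type 2 of 100 orders of the times, the real one included, gave at least 614 genes, with 658 as the highest other count. For the labelled mutant 1 of 100 gave at least 546 genes, with 166 as the highest other. For the difference in trend 2 of 100 exchanges gave at least 156 genes, with 327 as the highest other. Each of these exchanges also carried the strain difference at matched times into the spread or the slopes. The 2 in 100 therefore does not measure chance for a trend difference. The shares for the trends within a strain hold only if arrays are exchangeable. The median correlation of a gene's strain difference with that of the next time was 0.22, where independent values gave -0.11 in simulation, so values at successive times were not independent, and a drift between successive arrays of single cultures is not excluded as the source of these trends.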
